A study of Homo sapiens with 7 samples.

How the data were processed

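RNA was measured on 7 Agilent two-colour whole human genome arrays, each comparing a platinum-resistant cell line with the parental line it was selected from. The resistant line carried Cy5 and its parent Cy3 on every array, per the labels, so no dye swap exists and a dye effect specific to a gene cannot be separated from resistance. The deposited scanner files held 45015 features per array, of which 43376 were spots for 41000 distinct probes and 1639 were controls. Their spot and background intensity values were deposited on the scanner's linear scale, per the file headers, without normalisation. The same files held processed intensity values, background-subtracted, detrended and LOWESS-normalised by Feature Extraction, per the file headers. Their log10 ratio of the processed signals was computed by Feature Extraction, per the file headers, and lay within 0.22 of the ratio recomputed from those signals. Other deposited columns were flags for saturated, non-uniform and well-above-background spots and for control type, per the file headers. The headers name Feature Extraction version 9.5.1.1, whereas the submitters' processing notes name version 8.5.1. A deposited value table held the submitters' normalised log2 ratio of resistant over parental line. It was made in limma with quantile scaling and no background subtraction, per the submitters' processing notes. Its direction was checked against the scanner files, where r across spots was 0.804 to 0.897, and r was 0.968 to 0.988 with the stated method rerun. Probe coordinates are those of build hg17, per the file headers.

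The 6 oxaliplatin-selected lines formed 2 groups of 3, exposed for 4 h or 72 h, with 1 line of each schedule from each of the parents LoVo-92, LoVo-Li and A2780. The cisplatin-selected line ADDP, derived from A2780, formed a group of 1. Samples with the same number in the 2 oxaliplatin groups share a parent, per the labels. After removing each schedule's mean, r across genes between such lines was 0.51, 0.54 and 0.49, where simulated lines that share only a parental channel give 0.495. With no mean removed, r was 0.69 for LoVo-92, 0.54 for LoVo-Li and 0.52 for A2780, against 0.46, 0.48 and 0.43 in simulated lines with no shared change. The simulations assume equal spread in parent and line, and a larger parental spread would raise their values, so how much of r is shared change stays open. The 4 LoVo arrays lay on 1 slide and the 3 arrays of A2780 derivatives on another, so tumour type and slide cannot be told apart. Between 66.9% and 71.9% of probes were well above background for the resistant lines (27431 to 29474 probes), and between 64.5% and 71.2% for the parents (26431 to 29182 probes). At most 2 probes per array were saturated, and spike-in controls had slopes of 0.886 to 0.944 on their designed ratios. The SD of the difference between repeated parental channels was 0.11 to 0.19 on the log2 scale. The labels do not say whether repeated parental channels came from separate cultures. The number of arrays limits the precision.

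All values reported were recomputed from the scanner intensities with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table and version 2.0.0 of jsonlite. Background was corrected by normexp with an offset of 50, ratios were normalised within arrays by loess, and mean intensities were equalised between arrays by Aquantile. The probe with the highest mean intensity stood for its gene, a choice that affected 7513 genes with more than 1 probe. Genes were kept when a channel was well above background on at least 2 of the 7 arrays, which left 24308 of 30990. Of these, 15098 had the symbol of the reference table of gene names, and 9210 kept the name given in the file. Fits with 1 coefficient per parent or per schedule used the 24290 genes with enough values. The choices of test, gene lists, rules and alternatives were made before the data were examined, except where the text says otherwise.

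The mean log2 ratio of the 6 oxaliplatin-selected lines was tested against 0 in limma with the parent as a random block (consensus correlation 0.397). The 72 h lines were compared with the 4 h lines with the parent as a fixed block. The effect for each parent, its 2 lines against 0, came from 1 fit of all 6 arrays in which the parents share the estimate of spread. Differences between the effects of A2780 and LoVo, and of LoVo-Li and LoVo-92, were contrasts of that fit. These tests carry the spread between lines selected from 1 parent and leave out the spread of the parent culture itself, since both lines were compared with the same parent. Tests were two-sided with Benjamini-Hochberg adjustment over all genes, and the threshold was an adjusted p of 0.05. ADDP has 1 array and no test; genes at least 2-fold different with the brighter channel well above background were counted. A total of 33 gene lists were tested by camera in limma with a preset correlation of 0.01, again with an estimated correlation, and by fry, which tests whether a list's genes move on balance in 1 direction. For ADDP, the median of each list was ranked among 10000 random lists matched on intensity. Where the text gives a list's result, camera with the preset correlation is meant unless another test is named. No camera call held with an estimated correlation, where the smallest adjusted p of a called list was 0.335.

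Named genes have the largest absolute log2 change among genes past the threshold with the same sign on every array and the brighter channel well above background throughout. The rule takes up to 12 in each direction for the 6-line comparison and ADDP and up to 8 elsewhere, or the 5 largest where fewer than 5 passed, which are then said not to pass. For a difference between parents, the same sign was taken to mean that all arrays of 1 group lay above or below all of the other, and for the schedules that all 3 pairs had the same sign. Members of a list are its largest changes among those past the threshold, or its largest values. Where the dimmer channel was not well above background, a fold is a lower bound against the lowest well-above-background signal. Genes outside these rules are said to have been chosen after their values were seen. Uncharacterised gene names were left out of the naming, as were genes that can identify a person's sex, and a few other genes that met the rules are not reported here.

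Each step was tested on simulated data with the real arrays' intensities and spread within parents. Of 100 genes changed 2-fold and 100 changed 4-fold among 24290, the 6-line comparison recovered 70 and 95, and the comparison of schedules recovered 0 and 43. For the 6-line comparison, genes were drawn as independent and the spread between parents was a fixed multiple of that within parents. Its recovery therefore does not show how often a change shared by the real lines would be found. The parental effects recovered 34 and 77 for LoVo-92, 39 and 86 for LoVo-Li, and 40 and 78 for A2780. The A2780 minus LoVo difference recovered 25 and 64, and the LoVo-Li minus LoVo-92 difference 2 and 46. False calls numbered 0 to 11 per comparison. A list shifted by 0.5 in all 6 lines was called by camera in the 6-line comparison and for each parent. It was not called in the comparison of schedules or the differences between parents, where such a shift leaves no difference to find. Recovery of lists was therefore not tested in those comparisons. In the comparison of schedules, 1 of 32 unshifted lists was called, and in the others 0. Genes were drawn as independent in these simulations too. They therefore do not show how often camera with the preset correlation calls an unshifted list of correlated genes. With an estimated correlation the shifted list was called in the 6-line comparison but for none of the parents. Alternatives covered background and normalisation, the submitters' values, probe filters and averages, the variance model, the block, the slide, a schedule term, fold rules and leaving out each line. A correction for the G and C content of probes was added after seeing the data. The neighbour test took windows of 10 Mb with at least 20 genes and 100000 random draws of genes; it was also chosen after seeing the data. In simulations of 24290 genes it called 100 of 100 windows shifted by 0.5 and 6 of 100 unshifted windows at an unadjusted p under 0.05.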

Results

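Gene expression was measured in 7 platinum-resistant human cancer cell lines, each against its own parental line on a two-colour array. LoVo is a colorectal cancer line, represented by the sublines LoVo-92 and LoVo-Li, and A2780 is an ovarian cancer line. Each of these 3 parents gave 1 oxaliplatin-selected line exposed weekly for 4 h (4OHP) and 1 exposed weekly for 72 h (cOHP), at increasing concentrations. A seventh line, ADDP, was selected from A2780 with weekly 1 h exposures to cisplatin at 50 µM for 6 months. There were 3 arrays in each oxaliplatin group and 1 for cisplatin. Between 27431 and 29474 of 41000 probes were well above background in the resistant lines. Values are log2 ratios of resistant over parental line, with the standard error of the fit unless stated otherwise.

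The first question was what the oxaliplatin-resistant lines shared. Among the named genes, the largest shared fall was in ALDH1L2, a mitochondrial enzyme of folate metabolism. The largest shared rise was in AKR1C3, an aldo-keto reductase. ALDH1L2 was lower in 6 of 6 lines, with a mean log2 ratio of -3.01 ± 0.40 (n = 6 arrays) and single lines between -4.08 and -2.07. Its probe lies on chromosome 12 at 103916370 to 103916429 (hg17), and its other probe gave -1.22. AKR1C3 was higher in 6 of 6, at 1.52 ± 0.27, with single lines between 0.65 and 2.28. Neither passed the test over all genes, with an adjusted p of 0.646. The other large positive means, none past the threshold, were those of the cadherin CDH12 (1.37 ± 0.39), the Wnt receptor FZD1 (1.36 ± 0.48), the cell cycle kinase CDK6 (1.36 ± 0.44) and STEAP1 (1.32 ± 0.63). The other probe of FZD1 gave 0.08. Much of these means came from lines of 1 tumour type. FZD1 was at 3.41 and 2.52 and CDK6 at 2.83 and 3.02 in the A2780 lines, and the means of the 4 LoVo lines were 0.56 and 0.57, while CDH12 had a mean of 0.19 in the A2780 lines. STEAP1 rested largely on A2780/4OHP, at 4.08. Among lower genes, also none past the threshold, were the stress-response gene NUPR1 (-1.60 ± 0.35), TXNIP, which encodes an inhibitor of thioredoxin (-1.59 ± 0.55, with single lines between -3.77 and -0.076), and SYTL1 (-1.52 ± 0.27). KRTCAP3, at -1.67 ± 0.78, was low mainly in the LoVo-92 lines, at -4.11 and -4.94.

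Gene lists were called by camera with the preset correlation where single genes did not pass, though none of these calls held with an estimated correlation. All 35 measured proliferation genes had positive means, with a median of 0.44, and the list rose by camera (adjusted p = 9.85e-12, and adjusted p = 0.422 with an estimated correlation). Examples are MCM3 (0.96) and E2F1 (0.90). Of 36 Fanconi and homologous recombination genes, 29 had positive means, with a median of 0.26 and FANCA at 0.98 (adjusted p = 2.48e-05, and adjusted p = 0.414 with an estimated correlation). Targets of fluoropyrimidines, folate and irinotecan had 21 of 24 positive means, with a median of 0.33 (adjusted p = 2.41e-05, and adjusted p = 0.401 with an estimated correlation). Smaller rises by camera were found for heat shock genes (median 0.24), housekeeping genes (0.17), oxidative phosphorylation genes (0.16) and NRF2 targets (0.12), with adjusted p from 1.27e-04 to 0.0163. With an estimated correlation, these lists had adjusted p from 0.335 to 0.549. The housekeeping call held under all 15 alternatives run for lists (largest adjusted p 0.00775). Its median was between 0.086 and 0.34 in the single oxaliplatin-selected lines and 0.25 in ADDP. The resistant line was Cy5 on every array, so no alternative could separate these rises from a dye effect. The heat shock and oxidative phosphorylation calls held under 13 and the NRF2 call under 14. AKR1C3 was 1 of 29 NRF2 targets to pass when adjusted over the list alone, and BAG3, a co-chaperone, was 1 of 17 heat shock genes, at 0.60; neither passed over all genes. The heat shock call ended without LoVo-Li/4OHP or A2780/4OHP (adjusted p of 0.0571 and 0.140), the oxidative phosphorylation call without LoVo-Li/4OHP (0.0571) or with Feature Extraction's processed signals (0.0573) and the NRF2 call without LoVo-Li/cOHP (0.0789).

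Lists with lower means were the p53 targets and the unfolded protein and amino acid stress genes. Of 35 p53 targets, 26 had negative means, with a median of -0.46, PHLDA3 at -1.40, TP53INP1 at -1.04 and CDKN1A at -0.54 (adjusted p = 9.95e-06, and adjusted p = 0.335 with an estimated correlation). Of 32 stress genes, 28 had negative means, with a median of -0.79 (adjusted p = 5.40e-07, and adjusted p = 0.414 with an estimated correlation). This fall was mainly that of the A2780 lines, with medians of -1.997 and -1.77, and of LoVo-Li/4OHP, at -0.75; the median was -0.20 in LoVo-92/4OHP, -0.0099 in LoVo-92/cOHP and 0.22 in LoVo-Li/cOHP. With median centring in place of loess, these medians became 0.14 and 0.02 and both calls ended, with adjusted p of 0.485 and 0.202. Median centring also raised the median of all genes, to between 0.055 and 0.27 in these lines. A change of sign under it, here or for the lists below, need not be a reversal against other genes. HOX genes had a median of -0.18 (adjusted p = 0.033, and adjusted p = 0.401 with an estimated correlation), and their call ended without LoVo-Li/4OHP (0.0571). No call was made for the 15 platinum and copper transport genes (adjusted p = 0.859), the 15 ABC efflux genes (0.067) or the 17 mismatch repair genes (0.058). Copper transporter SLC31A1 had a mean of -0.38 ± 0.33, ABCB1, the P-glycoprotein gene, 0.86 ± 0.32, and the replication clamp PCNA, counted among mismatch repair genes, 1.01 ± 0.43. These means were not shared by all lines. SLC31A1 was at -1.80 and -1.15 in the A2780 lines and between -0.059 and 0.37 in the LoVo lines. ABCB1 was at 0.036 and 0.0072 in the A2780 lines and between 0.45 and 2.08 in the LoVo lines. PCNA was at 2.20 in LoVo-Li/4OHP and at -0.34 in LoVo-Li/cOHP. Leukocyte markers and fibroblast and endothelial markers, listed as signs of other cells, were not called either.

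**Figure D1:**
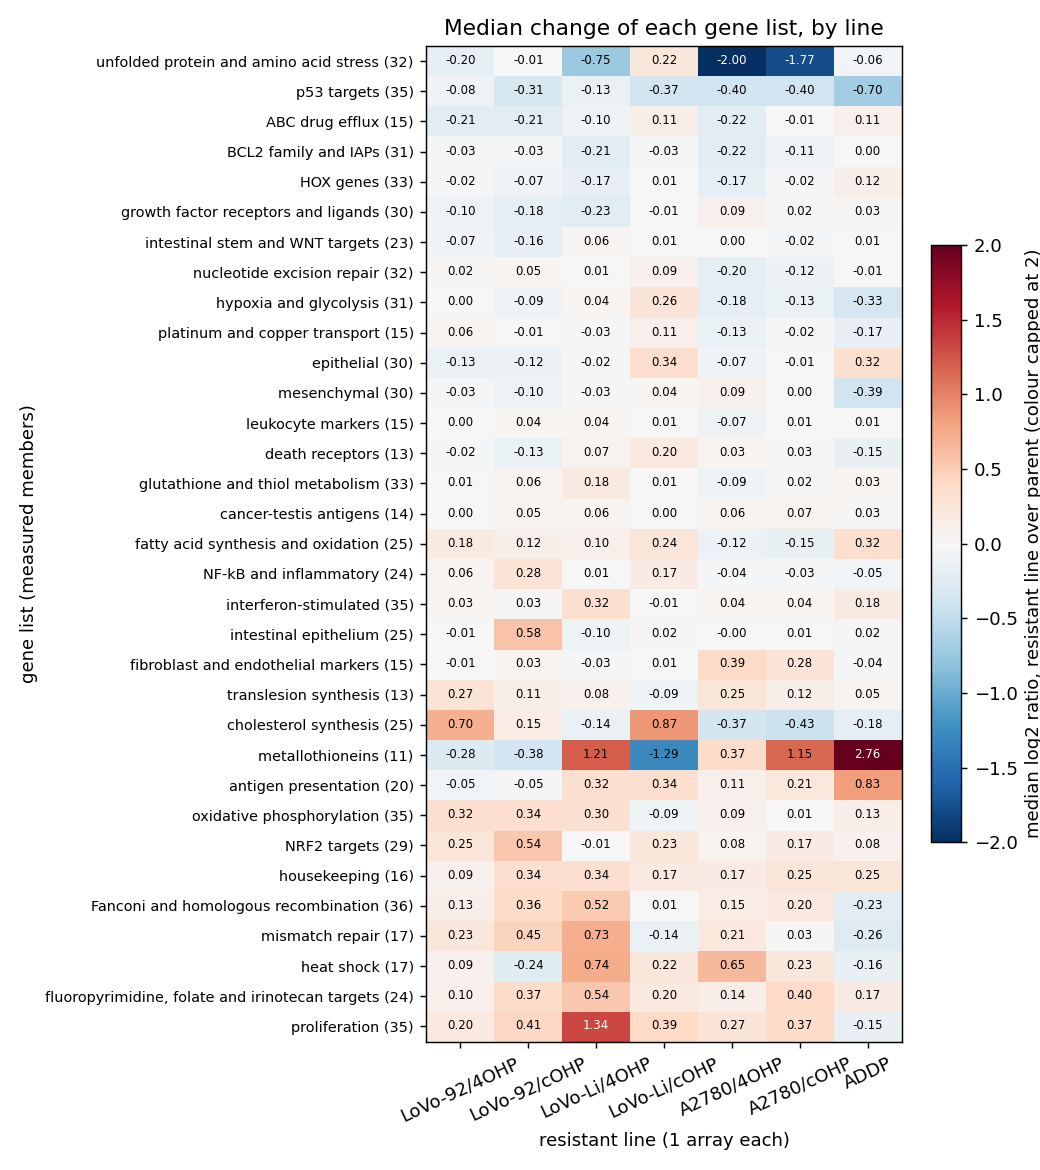
Each cell gives, as number and colour, the median log2 ratio (resistant over parental) of a gene list (vertical axis) in 1 of the 7 lines (horizontal axis, 1 array each). Proliferation medians lie above 0 in all 6 oxaliplatin-selected lines, from 0.20 to 1.34, and the stress list lies far below 0 in A2780/cOHP, at -1.77, and in A2780/4OHP.

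By limma, 0 genes passed the threshold across the 6 lines, while 1849 had an unadjusted p under 0.05, against 1215 from chance alone. Median centring, which moved the median ratio of all genes on an array to between 0.06 and 0.36, gave 6436 genes, of which 6324 were higher. Within the LoVo slide and within the A2780 slide, 0 genes passed, with 2622 and 4312 at an unadjusted p under 0.05.

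The second question was whether the weekly exposure time mattered. Comparing the 72 h line with the 4 h line of each parent, the largest positive differences were those of ERRFI1, an inhibitor of EGFR signalling (2.62 ± 0.43), the actin-binding TMSB4X (2.51 ± 1.47), S100P (1.89 ± 0.57), IL1B (1.64 ± 0.57) and the stress transcription factor ATF3 (1.62 ± 0.35). The largest negative ones were those of EGR1, an immediate early gene (-2.12 ± 0.69), WWC3 (-2.08 ± 0.35), TMEM98 (-2.0 ± 1.04), the Wnt inhibitor DKK1 (-1.83 ± 0.82) and PDE4B (-1.75 ± 0.78). Each had the same sign in 3 of 3 pairs, and none passed the threshold (n = 6 arrays, adjusted p = 0.935). By camera, stress genes were higher in 72 h lines (23 of 32 positive, median 0.40), heat shock genes lower (14 of 17 negative, median -0.30), both with an adjusted p of 0.00104, and epithelial genes higher (24 of 30, median 0.30, adjusted p = 0.00441). All 3 had an adjusted p of 0.784 with an estimated correlation. The stress call ended without the LoVo-Li lines (0.0592) and the epithelial call without the A2780 lines (0.139). All 11 metallothionein genes had negative differences, with a median of -0.65 (adjusted p = 0.00535, and adjusted p = 0.784 with an estimated correlation). That call rested on LoVo-Li, whose 4 h line had a median ratio of 1.21 and whose 72 h line had -1.29, and its direction turned without either line (adjusted p = 0.175); it also ended with Feature Extraction's processed signals (0.0567). Proliferation genes had 31 of 35 negative differences, with a median of -0.22 (adjusted p = 0.00601, and adjusted p = 0.856 with an estimated correlation), and without either LoVo-Li line the list was called in the other direction (1.43e-04). The remaining calls were small, with medians from -0.18 for p53 targets to 0.16 for intestinal epithelium genes and adjusted p from 0.0154 to 0.0383, and 0.784 with an estimated correlation. All of them ended without lines of LoVo-92 or LoVo-Li (adjusted p from 0.263 to 0.974), and all ended with Feature Extraction's processed signals (from 0.0567 to 0.457). The NF-kB and interferon calls also ended under the submitters' method, under loess without background correction and with the submitters' deposited values (0.201 to 0.394). The oxidative phosphorylation call ended with the deposited values (0.0585), and its direction turned without either LoVo-Li line (0.769). The NRF2 median of 0.12 turned to -0.13 with median centring. By limma, 0 genes passed, while 883 had an unadjusted p under 0.05, against 1214 from chance. Simulated 2-fold differences were recovered in 0 of 100 genes and 4-fold differences in 43 of 100 in this comparison, so that differences of such sizes could go undetected.

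In the LoVo-92 lines, the largest positive mean ratios were those of the chemokine receptor CXCR4 (3.25 ± 0.21, adjusted p = 0.0612), the secretory-cell proteins AGR2 (2.83 ± 0.34) and AGR3 (2.72 ± 0.37), AKR1C1 (2.80 ± 0.55) and the immunoglobulin transporter PIGR (2.49 ± 0.33). The lowest were those of KRTCAP3 (-4.52 ± 0.23, adjusted p = 0.0612), the tight junction gene CLDN3 (-3.80 ± 0.30), ZNF22 (-3.30 ± 0.28) and GARIN5A (-3.16 ± 0.40), while TCEAL9 was at least 15-fold lower. Each value is the mean of 2 arrays with the same sign, and none passed the threshold. Other probes gave -0.61 for CLDN3 and -0.71 for ZNF22. Oxidative phosphorylation genes rose by camera (32 of 35 positive, median 0.31, adjusted p = 2.73e-07), with 9 higher and 1 lower when adjusted over the list alone and 0 over all genes. NRF2 targets rose too (median 0.45, adjusted p = 0.00157), with 9 higher and 1 lower when adjusted over the list alone and 0 over all genes. The probes of AKR1C1 and AKR1C3 belong to a family of closely similar sequences, so cross-hybridisation between them is not excluded. Intestinal epithelium genes, which include FABP1 (2.24 ± 0.35) and TFF3 (1.75 ± 0.12), had 20 of 25 positive means and a median of 0.29 (adjusted p = 4.05e-04). All 3 lists had an adjusted p of 0.590 with an estimated correlation. Other lists that rose were cholesterol synthesis (median 0.38), Fanconi and homologous recombination (0.31), proliferation (0.27), housekeeping (0.24), NF-kB (0.20), mismatch repair (0.38), translesion synthesis (0.21), the fluoropyrimidine list (0.26) and fatty acid metabolism (0.14), with adjusted p from 4.50e-04 to 0.0477. Lower by camera were p53 targets (median -0.19), growth factor receptors and ligands (-0.17) and epithelial genes (-0.11), with adjusted p from 0.0158 to 0.0398, and the p53 and epithelial medians turned to 0.51 and 0.48 with median centring. All genes then had medians of 0.27 in LoVo-92/4OHP and 0.26 in LoVo-92/cOHP. With an estimated correlation, these 12 lists had adjusted p from 0.590 to 0.755. Without LoVo-92/4OHP or without LoVo-92/cOHP, 12 of the 15 calls ended, those for oxidative phosphorylation, NRF2 and NF-kB genes excepted, with adjusted p from 0.0742 to 0.303. The epithelial, fatty acid, fluoropyrimidine and mismatch repair calls also ended under the submitters' method, under loess without background correction, with Feature Extraction's processed signals and with the submitters' deposited values (0.0699 to 0.201), and the NF-kB, p53 and epithelial calls ended with median centring (0.579, 0.635 and 0.865). Of the 15 calls, those for oxidative phosphorylation and NRF2 genes alone held under all 15 alternatives run for lists. By limma, 0 genes passed, while 3862 had an unadjusted p under 0.05. The submitters' own values gave 243 genes, 44 higher and 199 lower. Without background correction, loess gave 284.

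In the LoVo-Li lines, 597 genes passed the threshold, 348 higher and 249 lower, of which 175 and 141 changed at least 2-fold (n = 2 arrays). DACH1, a transcription factor of the retinal determination network, rose by 3.62 ± 0.32 (adjusted p = 0.0355), the ephrin receptor EPHA3 by 2.67 ± 0.14 and CDH12 by 2.54 ± 0.19. Also higher were TECPR2 (2.41), embryonic haemoglobin HBE1 (2.21), the condensin subunit NCAPG2 (2.16), SEMA6A (2.01) and CSF1R (1.86). The caveolar protein gene CAVIN3 changed by -4.49 ± 0.13 and PYCARD, the inflammasome adaptor, by -4.00 ± 0.10, both with an adjusted p of 0.00176. ALDH1L2 changed by -3.51 ± 0.47, the lysyl oxidase LOXL4 by -3.13 ± 0.13, the cytokine IL33 by -2.99 ± 0.24, PF4 by -2.86 and RNF182 by -2.80, while the collagen gene COL6A5 was at least 9.01-fold lower. Other probes of CAVIN3 and LOXL4 gave -0.54 and -0.46. Among drug efflux genes, ABCB1 rose by 1.86 ± 0.17 (adjusted p = 0.0373) and ABCG2 changed by -1.21 ± 0.11 (adjusted p = 0.0369). ABCC2, at -2.21, passed when adjusted over the list alone.

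All 35 proliferation genes had positive means in the LoVo-Li lines, with a median of 0.83 (adjusted p = 3.41e-10). MCM2 (1.71 ± 0.27) and CDC20 (1.57 ± 0.21) passed over all genes, and 19 passed when adjusted over the list alone. The median was 1.34 in LoVo-Li/4OHP and 0.39 in LoVo-Li/cOHP. Antigen presentation genes rose by camera (18 of 20 positive, median 0.49, adjusted p = 0.00581), with 2 higher when adjusted over the list alone and 0 over all genes. Cholesterol synthesis genes rose (23 of 25, median 0.48, adjusted p = 0.0083). Heat shock genes rose as well (median 0.50, adjusted p = 0.0127), with the mitochondrial chaperone HSPD1 at 1.34 ± 0.20 and HSP90AB1 at 0.73 ± 0.09. Fluoropyrimidine list genes (median 0.43) and Fanconi genes (median 0.26, with SLX4 at 0.89 past the threshold) had adjusted p of 0.00858 and 0.0208. The p53 targets were lower (24 of 35 negative, median -0.35, adjusted p = 0.0386), though their median became 0.21 with median centring, where the call ended (0.597). All genes then had medians of 0.23 in LoVo-Li/4OHP and 0.22 in LoVo-Li/cOHP. These 7 lists had an adjusted p of 0.912 with an estimated correlation. Calls ended without LoVo-Li/4OHP for heat shock (0.189), fluoropyrimidine (0.295) and Fanconi genes (0.823), and without LoVo-Li/cOHP for cholesterol genes (0.974) and p53 targets (0.595), and the Fanconi call also ended with Feature Extraction's processed signals (0.05002). Stress genes had a median of -0.75 in LoVo-Li/4OHP and 0.22 in LoVo-Li/cOHP and were not called. The count of genes depended on single arrays, at 5 without either LoVo-92 line, 10 without either A2780 line, 0 without LoVo-Li/4OHP (3595 at an unadjusted p under 0.05) and 1051 without LoVo-Li/cOHP. Median centring gave 5139 higher and 362 lower, and Feature Extraction's processed signals gave 4 higher and 11 lower.

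In the A2780 lines, 821 genes passed the threshold, 375 higher and 446 lower, of which 241 and 302 changed at least 2-fold (n = 2 arrays). The strongest rises were those of the folate hydrolase FOLH1 (5.24 ± 0.36, 37.8-fold, adjusted p = 0.00772), neurotensin (NTS, 5.14 ± 0.69), FAM111A (5.01 ± 0.32), the membrane protein gene BASP1 (4.86 ± 0.12), EPDR1 (4.77 ± 0.51), the matrix metalloproteinase MMP10 (4.75 ± 0.52) and the adhesion molecule CEACAM1 (4.61 ± 0.45). FOLH1B, at 4.43, is a close paralog of FOLH1, and the array cannot exclude that 1 transcript bound both probes. The largest falls were those of ATF3 (-4.75 ± 0.67, adjusted p = 0.0356), TRIB3 (-4.09 ± 0.62), the receptor IL21R (-3.98), SPOCK2 (-3.98), urokinase (PLAU, -3.97 ± 0.10, adjusted p = 0.00127) and FUT1 (-3.90). The other probe of EPDR1 gave 0.65. ATF3 and TRIB3 belong to the unfolded protein and amino acid stress list, of which 28 of 32 genes had negative means, with a median of -1.85. In that list 16 genes fell over all genes and 26 when adjusted over the list alone, among them CHAC1 (-3.79 ± 0.53) and STC2 (-3.32 ± 0.33). The list fell by camera (adjusted p = 3.87e-14, and adjusted p = 0.754 with an estimated correlation) and by fry (adjusted p = 0.0302).

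**Figure D2:**
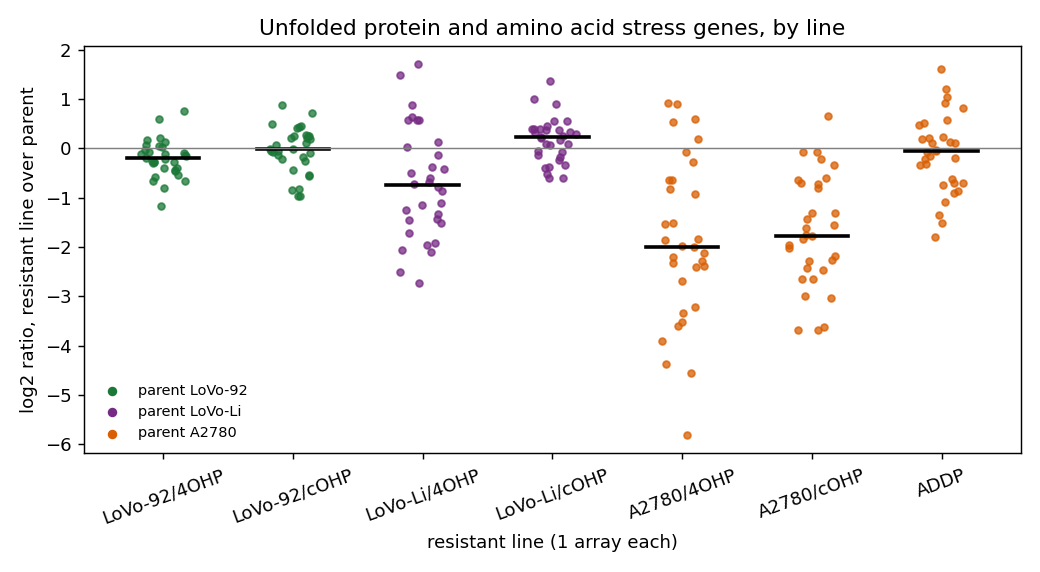
Each point is the log2 ratio (vertical axis, resistant over parental) of 1 unfolded protein and amino acid stress gene in 1 line (horizontal axis, 1 array each), and each black bar is the median of the list. ATF3 lies at -5.81 in A2780/4OHP and at 0.92 in ADDP, which shares the parent.

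Targets of p53 were also lower in the A2780 lines, with 28 of 35 negative means, a median of -0.48 and 4 past the threshold, namely GDF15 (-3.22 ± 0.53), SESN2 (-1.88 ± 0.29), PLK2 (-1.77 ± 0.24) and PERP (-1.40 ± 0.17). SESN2 stands in the stress list as well. Adjusted over the list alone, 2 were higher and 9 lower (adjusted p = 0.00148, and adjusted p = 0.754 with an estimated correlation). In the platinum and copper transport list, copper importer SLC31A1 changed by -1.48 ± 0.18, the volume-regulated channel subunit LRRC8D by -1.18 ± 0.17 and TMEM205 by -1.01 ± 0.17, while the extrusion transporter SLC47A1 rose by 1.56 ± 0.19, all with adjusted p from 0.0265 to 0.0497. The efflux pump gene ABCC5 changed by -0.98 ± 0.12 and mismatch repair gene MSH6 by 0.68 ± 0.11. Heat shock genes (median 0.39, with HSPA8 at 1.96) and the fluoropyrimidine list (median 0.27, with DPYD at 1.18) rose by camera, with adjusted p of 0.0357 and 0.0367. Cholesterol synthesis genes were lower (median -0.43, adjusted p = 0.0357, with the regulator SREBF2 at -1.94 and TM7SF2 at -1.83 past the threshold), though the list's median became 0.21 with median centring. All genes then had medians of 0.25 in A2780/4OHP and 0.055 in A2780/cOHP. These 3 lists had an adjusted p of 0.754 with an estimated correlation. Calls ended without A2780/cOHP for p53 targets (0.0737), cholesterol genes (0.234) and the fluoropyrimidine list (0.504), and without A2780/4OHP for heat shock genes (0.280). The cholesterol, fluoropyrimidine and heat shock calls also ended under the submitters' method, under loess without background correction, with Feature Extraction's processed signals and with the submitters' deposited values (0.0506 to 0.0691), and the cholesterol call with median centring (0.526). By fry, nucleotide excision repair genes were lower and translesion synthesis genes higher, both with an adjusted p of 0.0197, whereas camera gave 0.0745 and 0.362. The mesenchymal regulator TWIST1 rose by 2.02 ± 0.17 and CCN1 changed by -3.45 ± 0.24, in a mesenchymal list that was not called. Fibroblast and endothelial markers, also not called, had medians of 0.39 and 0.28 in the 2 lines. The count was 51 without either LoVo-92 line, 416 without A2780/4OHP, 1895 without A2780/cOHP and 0 with a variance trend and robust estimation, where 5516 genes had an unadjusted p under 0.05. Median centring gave 3123 higher and 336 lower.

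**Figure D3:**
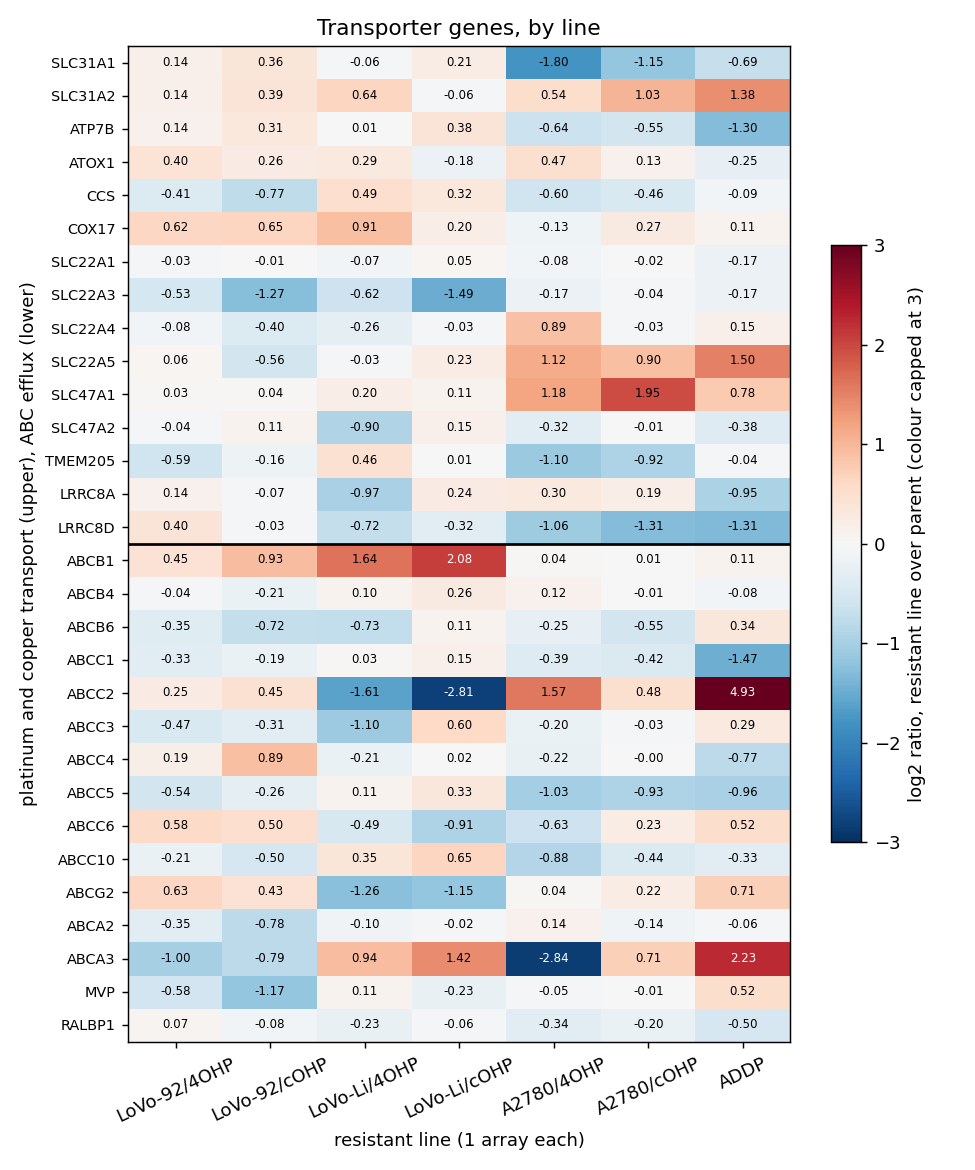
Each cell gives, as number and colour, the log2 ratio (resistant over parental) of a platinum and copper transport gene (upper) or ABC efflux gene (lower) in 1 line (horizontal axis, 1 array each). ABCC2 is at 4.93 in ADDP and at -2.81 in LoVo-Li/cOHP, and SLC31A1 is at -1.15 in A2780/cOHP.

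The series contrasts ovarian with colorectal lines. The A2780 effect differed from the mean LoVo effect in 225 genes, 108 with a higher and 117 with a lower ratio in A2780 lines (n = 6 arrays). Those with the largest positive difference were BASP1 (4.92 ± 0.14, adjusted p = 0.00295), FAM111A (4.74 ± 0.39), the potassium channel subunit KCNMB4 (4.54 ± 0.17), carboxypeptidase E (CPE, 4.54 ± 0.36), the actin-associated PALLD (4.09 ± 0.23), ATP1B1 (3.54), RBM47 (3.41) and TENT5A (3.35). The largest negative ones were PLAU (-4.19 ± 0.12, adjusted p = 0.00295), SPOCK2 (-4.01), IL21R (-3.87), SMCR5 (-3.73), STC2 (-3.61), LIMS3 (-3.56), the neuropeptide galanin (GAL, -3.51) and LHX1 (-3.47). Ratios of stress genes were lower in A2780 lines than in LoVo lines (29 of 32, median -1.53, adjusted p = 1.19e-11). Of these genes, 20 were lower when adjusted over the list alone and 2 over all genes. Cholesterol synthesis genes were lower too (24 of 25, median -0.93, adjusted p = 2.64e-06), with 7 when adjusted over the list alone and 0 over all genes. Smaller differences were called for NF-kB genes (median -0.29, adjusted p = 0.0108) and proliferation genes (median -0.33, adjusted p = 0.026). These 4 lists had an adjusted p of 0.869 with an estimated correlation. The NF-kB call ended without A2780/cOHP (0.185), and the proliferation call without LoVo-Li/4OHP (0.711), LoVo-92/cOHP (0.0903), A2780/4OHP (0.123) or A2780/cOHP (0.137). The proliferation call held in 7 of 15 alternatives, ending also under the submitters' method (0.168), under loess without background correction (0.0812), with Feature Extraction's processed signals (0.146) and with the submitters' deposited values (0.0744). Tumour type and slide cannot be told apart here. The count was 0 without LoVo-92/4OHP or LoVo-92/cOHP (3575 and 2823 at an unadjusted p under 0.05), 20 without LoVo-Li/4OHP, 17 without LoVo-Li/cOHP, 1407 without A2780/cOHP and 0 with a variance trend and robust estimation, where 4718 genes had an unadjusted p under 0.05.

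The 2 LoVo sublines also differed in their response. Between LoVo-Li and LoVo-92, 440 genes differed, 332 with a higher and 108 with a lower ratio in LoVo-Li lines (n = 4 arrays). Higher were DACH1 (5.09 ± 0.45, adjusted p = 0.0398), KRTCAP3 (4.24 ± 0.32), HBE1 (3.94), the histone chaperone HIRA (3.43), the deubiquitinase BAP1 (3.42), CLDN3 (3.35), LTBR (3.15) and MAGED1 (3.13). Lower were AGR2 (-4.66 ± 0.48, adjusted p = 0.04), CAVIN3 (-4.63 ± 0.18), CXCR4 (-3.25), PPP3R1 (-3.03), SBSPON (-2.97), IL33 (-2.95) and PLAAT2 (-2.45). Among lists, ratios were higher in LoVo-Li lines for antigen presentation (18 of 20 positive, median 0.60, adjusted p = 0.00768) and proliferation genes (median 0.51, adjusted p = 0.00871). They were also higher for heat shock (0.75) and epithelial genes (0.43), and lower for intestinal epithelium (-0.39) and oxidative phosphorylation genes (-0.31). These last 4 lists had an adjusted p of 0.0137. With an estimated correlation, all 6 lists had adjusted p from 0.915 to 1.00. Of the 6 calls, antigen presentation alone held without any one of the 6 lines (largest adjusted p 0.0361), and proliferation genes turned direction without LoVo-Li/4OHP. The intestinal epithelium and oxidative phosphorylation calls also ended with Feature Extraction's processed signals (0.0792 and 0.133). The 332 genes with a higher response had on average 29.2 G and C bases in their 60-base probes, against 26.5 for all genes. The count was 0 without any one of the 6 lines (3112 to 5857 at an unadjusted p under 0.05) and 0 with a schedule term, where 5076 genes had an unadjusted p under 0.05, and the submitters' method gave 704 higher and 385 lower.

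**Figure D4:**
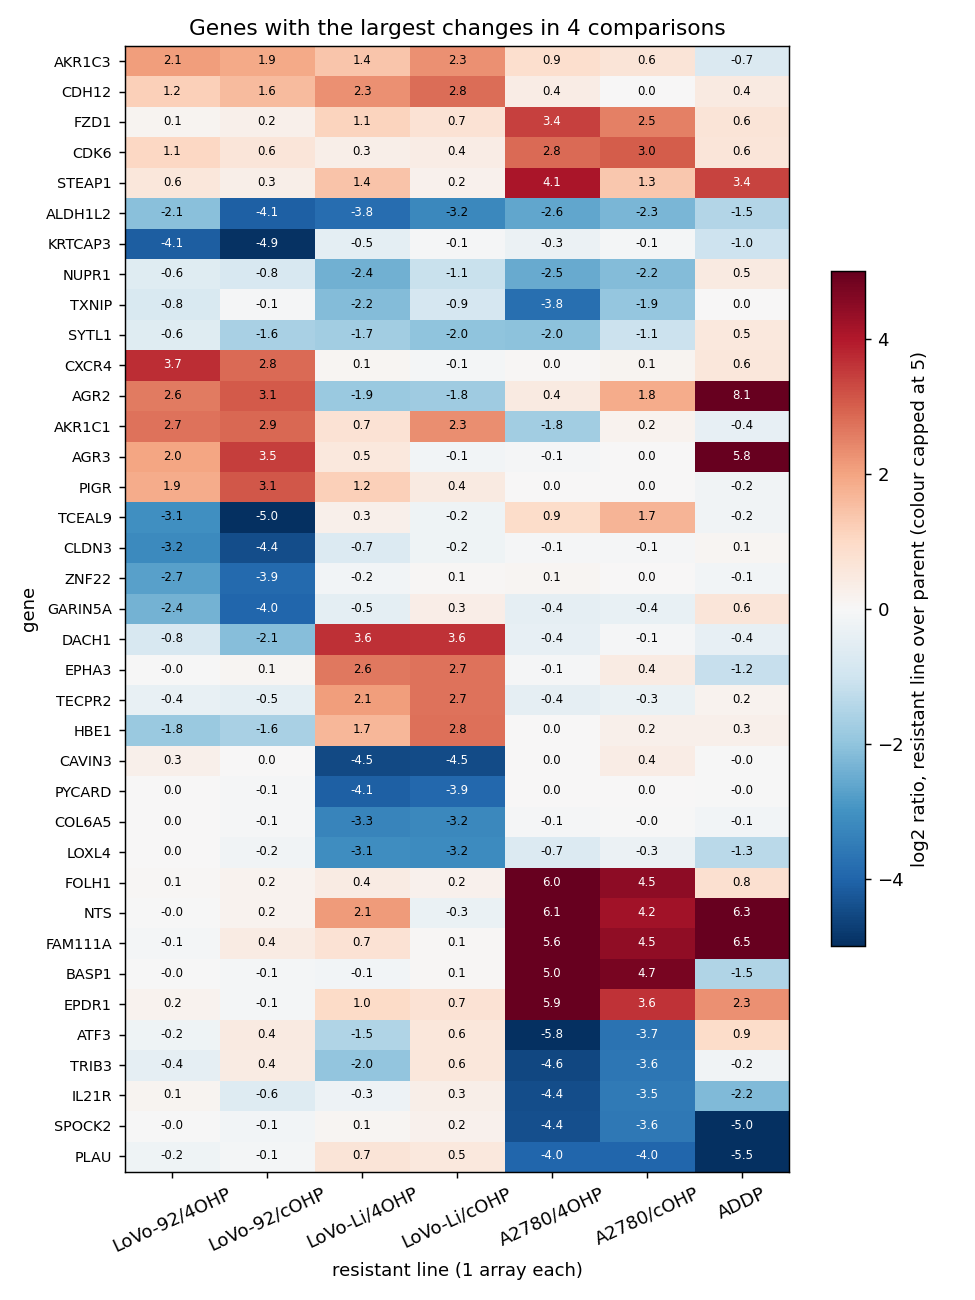
Each cell gives, as number and colour, the log2 ratio (resistant over parental) of a named gene (vertical axis) in 1 of the 7 lines (horizontal axis, 1 array each). ALDH1L2 lies below 0 in every line, from -4.08 to -1.48, whereas BASP1 is at 5.00 and 4.73 in the A2780 oxaliplatin-selected lines and at -1.49 in ADDP.

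Cisplatin carries ammine and chloride ligands on its platinum, whereas oxaliplatin has a diaminocyclohexane carrier and an oxalate leaving group. The cisplatin-selected ADDP differed from A2780 by at least 2-fold in 3226 genes (13.3%), 1832 higher and 1394 lower, in 1 array without replicate or test. Median centring gave 5875 higher and 931 lower. Highest were SYNPO2 (8.31), AGR2 (8.07), annexin ANXA1 (7.84), the melanocyte enzyme TYRP1 (7.38), the sulfide oxidising enzyme SQOR (7.31), S100A10 (7.02), the laminin LAMB1 (7.01), FLRT3 (6.94), TMEM125 (6.87) and TMSB4XP8 (6.60), with the epithelial factor KLF5 at least 128-fold and MAL2 at least 106-fold higher. S100A10 gave 0.15 on its other probe, and TMSB4XP8 is a pseudogene whose probe can bind TMSB4X. Lowest were ARMCX2 (-9.49), the imprinted gene MEST (-7.99), DKK1 (-7.69), the matrix genes POSTN (-7.33) and SPARC (-6.27), GPM6A (-6.90), the mesenchymal factor SNAI2 (-6.14), CREB5 (-5.97), PCDH7 (-5.97), GRIN3A (-5.89), TLE4 (-5.78) and MXRA8 (-5.72). The other probe of SNAI2 gave -0.92.

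Metallothioneins, which bind metals, had a median of 2.76 in ADDP, with 8 of 11 at least 2-fold higher, MT2A at 3.79 and MT1G at 3.48, and no random list reached that median. These genes are close in sequence and their probes are not independent. Antigen presentation genes had a median of 0.83, above all random lists, with HLA-F at 3.92. Epithelial genes, at 0.32 with EPCAM at 6.57 and CDH1 at 4.02, stood at percentile 99.5, and fatty acid genes, at 0.32 with CPT1A at 2.16, at percentile 99.2. Of the 30 epithelial genes, 9 were at least 2-fold higher and 3 at least 2-fold lower. Targets of p53 had a median of -0.70, with 14 of 35 at least 2-fold lower and 1 higher, PLK2 at -5.17, PHLDA3 at -5.03 and GDF15 at -4.50. Mesenchymal genes had a median of -0.39, with 12 of 30 at least 2-fold lower and 4 higher, and no random list lay below either median. Hypoxia and glycolysis genes (-0.33, percentile 0.08), Fanconi genes (-0.23, percentile 0.84) and mismatch repair genes (-0.26, percentile 3.68) had medians that turned to 0.55, 0.50 and 0.57 with median centring. All genes in ADDP then had a median of 0.36. The efflux pump gene ABCC2 was at 4.93 in ADDP. In the same size rule, A2780/4OHP had 1170 higher and 1333 lower genes, and A2780/cOHP 613 higher and 673 lower. That gap between the A2780 lines came with the normexp background correction. The totals of 2503 and 1286 were 2471 and 2529 with loess without it, 2444 and 2514 under the submitters' method and 2994 and 2985 with their deposited values. Feature Extraction's processed signals, background-subtracted in another way, gave 4862 and 4673, and median centring after normexp gave 5261 and 2072. Drug, dose and exposure time all differ between ADDP and the oxaliplatin-selected lines, so these values stand side by side.

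**Figure D5:**
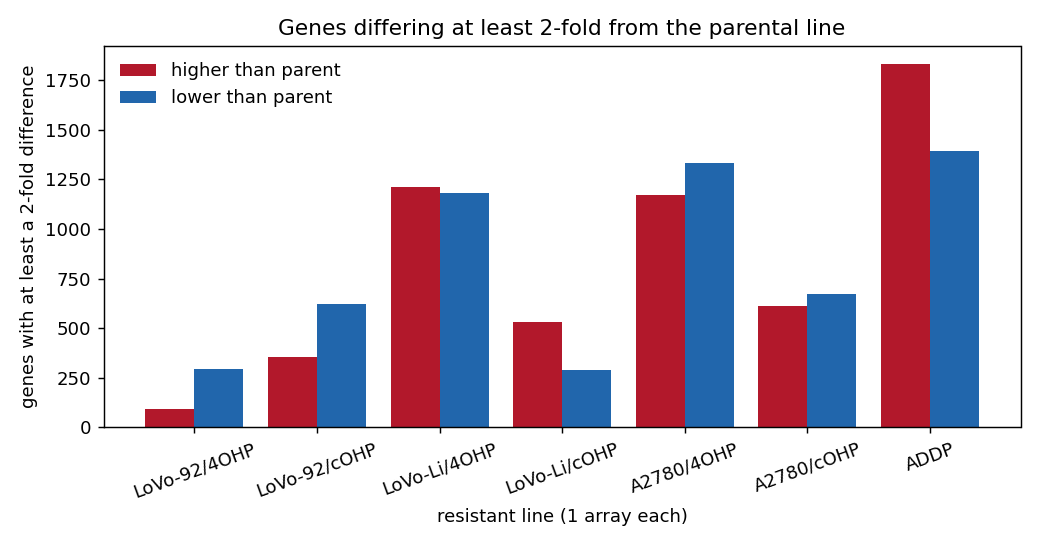
The bars show the number of genes (vertical axis) at least 2-fold higher (red) or lower (blue) in each resistant line (horizontal axis, 1 array each) than in its parent. Counts run from 92 higher and 294 lower in LoVo-92/4OHP to 1832 higher and 1394 lower in ADDP. They depend on the normexp background correction. Loess without it gave totals of 777 in place of 386 for LoVo-92/4OHP and 2529 in place of 1286 for A2780/cOHP, with 823 in place of 819 for LoVo-Li/cOHP.

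All 3 A2780 derivatives shared 132 genes at least 2-fold higher and 189 lower, where 2.22 and 2.12 would be shared if the lines were independent. The lines were compared with the same parent, however, and simulated lines with no shared change but a shared parental value gave 100 and 79. Across genes, r with ADDP was 0.31 for A2780/4OHP and 0.39 for A2780/cOHP, below the 0.42 of the simulated lines for each pair. The shared counts and r are those with the normexp correction. With it A2780/cOHP had 1286 genes at least 2-fold different, against 2529 with loess without it. Shared higher genes included FAM111A, at 5.56, 4.45 and 6.5 in A2780/4OHP, A2780/cOHP and ADDP, and NTS, at 6.10, 4.18 and 6.27. Shared lower genes included PLAU, at -3.97, -3.97 and -5.47.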

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

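The correction for probe content, the split of the LoVo difference into resistant and parental parts, both tests of the stress genes and the test of the A2780 parental preparation on chromosome 19 were chosen only after the results were seen.

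The response to selection differed between A2780 and LoVo lines in 225 genes by the test of the difference itself, a contrast confounded with the slide. Differences were positive for BASP1 (4.92), FAM111A (4.74), KCNMB4 (4.54), CPE (4.54), PALLD (4.09), ATP1B1 (3.54), RBM47 (3.41) and TENT5A (3.35). They were negative for PLAU (-4.19), SPOCK2 (-4.01), IL21R (-3.87), SMCR5 (-3.73), STC2 (-3.61), LIMS3 (-3.56), GAL (-3.51) and LHX1 (-3.47). By camera, the lists that differed were stress (-1.53), cholesterol synthesis (-0.93), proliferation (-0.33) and NF-kB genes (-0.29), given as medians.

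Lower unfolded protein and amino acid stress genes in the A2780 oxaliplatin-selected lines, with a median of -1.85 over both, had the smallest camera p of any list. Were the A2780 parental RNA itself rich in stress transcripts, or the slide shifted as a whole, ADDP might show the same fall, since it shares both parent and slide. The list's median in ADDP was -0.060 with quartiles at -0.70 and 0.30, and with median centring it was 1.04. This argues against neither explanation firmly, because ADDP is 1 array of a line selected with another drug and may carry raised stress genes of its own. Loss of the stress programme in the oxaliplatin-selected lines stays open beside them, as untested.

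The LoVo sublines differed in their response in 440 genes by the test of the difference itself. Differences, LoVo-Li minus LoVo-92, were positive for DACH1 (5.09), KRTCAP3 (4.24), HBE1 (3.94), HIRA (3.43), BAP1 (3.42), CLDN3 (3.35), LTBR (3.15) and MAGED1 (3.13). They were negative for AGR2 (-4.66), CAVIN3 (-4.63), CXCR4 (-3.25), PPP3R1 (-3.03), SBSPON (-2.97), IL33 (-2.95) and PLAAT2 (-2.45). List medians that differed were heat shock (0.75), antigen presentation (0.60), proliferation (0.51), epithelial (0.43), intestinal epithelium (-0.39) and oxidative phosphorylation genes (-0.31).

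For this difference, probe content was a candidate technical cause, since r across genes between ratio and G and C content was -0.32 in LoVo-92/4OHP and 0.12 in LoVo-Li/cOHP. After a correction for it, 316 genes kept their call and direction, which argues against probe content as the whole cause. Parental RNA alone was the other candidate, since the parental channels differed by a median of -0.87 over the 332 genes with a higher response in LoVo-Li lines and of 0.85 over the 108 with a lower one. The resistant lines themselves differed over those genes by medians of 0.77 (quartiles 0.46 and 1.07) and -0.50 (quartiles -1.13 and -0.020). DACH1, with the largest difference among the named genes (5.09), differed by -5.07 between the parents, LoVo-Li minus LoVo-92. Antigen presentation genes, at a median of 0.60, had a parental median of -0.65. For these the parental difference was about as large, with the opposite sign. Genes picked for a large difference of ratios tend to show both parts whatever the cause, so the medians over the picked genes leave parental RNA open. A smaller part from probe content stays open too, as does a biological difference between the sublines, which was not tested.

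In A2780/4OHP, 49 genes on chromosome 19 between 20 and 30 Mb (hg17) had a median of -0.68, with 42 below 0, and the permutation p was 1e-05, the smallest that 100000 draws can give, or 0.019 after multiplying by the 1918 windows and lines tested. Many are zinc finger genes, and cross-hybridisation across that family might shift them together. Zinc finger genes elsewhere (641) had a median of -0.050 in that line, against -1.33 for the 21 in the window, which argues against a family-wide effect. The 28 genes of the window with neither zinc finger name nor description had a median of -0.30 (quartiles -0.91 and -0.047, with 21 below 0). These carry only clone, probe or provisional names and may hold zinc finger sequence themselves, so binding among the window's own members stays open. The parental preparation is argued against as the whole cause by medians of -0.040 in A2780/cOHP and -0.11 in ADDP, both set against A2780 too. The window's 21 zinc finger genes had lower medians there, of -0.21 and -0.14, so a smaller part from the parental preparation stays open. Their medians were also -0.20 in LoVo-Li/4OHP and -0.27 in LoVo-Li/cOHP, against 0.0058 in LoVo-92/4OHP and -0.022 in LoVo-92/cOHP. A loss of DNA or silencing of the region in A2780/4OHP is a hypothesis that expression arrays cannot test.

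Among 43 groups of the 6 oxaliplatin-selected lines tested for a line far from the others, 6 had one, where chance gives about 1 in 20. STEAP1 was at 4.08 in A2780/4OHP, against 0.21 to 1.41 in the others. The proliferation list had a median of 1.34 in LoVo-Li/4OHP, against 0.20 to 0.41. Epithelial genes had 0.34 in LoVo-Li/cOHP, against -0.13 to -0.01. Intestinal epithelium genes had 0.58 in LoVo-92/cOHP, against -0.10 to 0.02. Interferon-stimulated genes had 0.32 in LoVo-Li/4OHP, against -0.01 to 0.04. Leukocyte markers had -0.069 in A2780/4OHP, against 0.00 to 0.04.

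The 10 splits of the 6 lines into 3 and 3 are too few for a share under 0.05. The real split of 72 h against 4 h gave 0 genes by limma (883 at an unadjusted p under 0.05), all 10 splits gave at least as many, and the highest other gave 348. Splits that part all 3 pairs of lines with a shared parent gave 0, as the real one did. The highest count came from splits that part a single pair. With the parent as a fixed block, such a split rests on the difference between the lines of that pair. It is therefore not a comparison of parents.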

How the results depend on the processing

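The probe G and C correction was chosen after the data were seen, and the other alternatives before. Counts below are of genes past the threshold unless stated, and where no cause is named, the cause was not tested. Calls and directions of single named genes stayed as reported in 1389 of the values computed for them, fell below the threshold in 360, newly passed it in 46 and moved without a call in 46; none past the threshold reversed. Across oxaliplatin lines and for the schedules, the count of 0 by limma held under the other alternatives run, except as given next. The submitters' method without background correction gave 265 for LoVo-92, 2547 for A2780, 1223 for the A2780 minus LoVo difference and 1089 for the LoVo-Li minus LoVo-92 difference. Loess without background correction gave 284, 2558, 1225 and 976 in that order. The submitters' deposited values gave 243, 2636, 1288 and 858, and 326 for LoVo-Li. Feature Extraction's processed signals gave 1 across the 6 lines, 93 for LoVo-92, 15 for LoVo-Li, 1998 for A2780, 1031 for A2780 minus LoVo, 18 for LoVo-Li minus LoVo-92, and 5714 genes at least 2-fold different in ADDP. Median centring gave 6436 across the 6 lines, 6860 for LoVo-92, 5501 for LoVo-Li, 3459 for A2780, 181 for LoVo-Li minus LoVo-92, 6806 for ADDP and 92 called lists, against 58 as reported; it leaves the median of all genes above 0, so most of its calls are higher. Of the main counts, 795 of the 821 A2780 genes passed in the same direction with the submitters' method, and 431 of the 440 genes of the LoVo difference. A variance trend with robust estimation gave 0 for A2780, 0 for A2780 minus LoVo (5516 and 4718 at an unadjusted p under 0.05) and 1117 for LoVo-Li minus LoVo-92. A schedule term, which takes away a degree of freedom, gave 4 for LoVo-Li, 341 for A2780, 13 for A2780 minus LoVo and 0 for LoVo-Li minus LoVo-92 (5076). A rule of 3-fold gave 1592 genes in ADDP and a rule of 1.5-fold gave 6523. Without a block, 0 genes passed across the 6 lines and 0 for the schedules, with 3437 and 208 at an unadjusted p under 0.05. Leaving out each of the 6 lines gave 0 to 0 across the 6 lines, for the schedules, for LoVo-92 and for LoVo-Li minus LoVo-92 (unadjusted p under 0.05 in 1067 to 2372, 655 to 963, 1317 to 4608 and 3112 to 5857 genes), 0 to 1051 for LoVo-Li, 51 to 1895 for A2780, 0 to 1407 for A2780 minus LoVo and 51 to 73 called lists; in these fits a lone line of a parent is assumed to vary like the others. With slide as a random block (correlation 0.0529) 0 passed across the 6 lines, with 2910 at an unadjusted p under 0.05. Genes near background limit the folds: between 64.5% and 71.9% of probes per channel were well above background, and a fold against a channel that was not is a lower bound.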

Other observations

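The test of windows of neighbouring genes was chosen only after the data were seen, and the comparison of parents was planned as values without a test.

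The parental sublines LoVo-Li and LoVo-92 differed widely before selection. Over 21688 genes in the Cy3 channels, 1246 were at least 2-fold higher in LoVo-Li and 1406 at least 2-fold lower, as means of 2 arrays each, and the labels do not say whether these came from separate cultures. LY6K, a GPI-anchored surface protein, was at least 390-fold higher in LoVo-Li, the esterase BCHE at least 257-fold and GPM6A at least 109-fold, while the small heat shock gene HSPB1 differed by 7.36, CLEC2B by 6.77 and RAMP1 by 6.47. Lower in LoVo-Li were IGFBP2 (-7.44), REG4, a secreted lectin of the gut (-6.77), superoxide dismutase SOD3 (-6.40), TGFBI (-6.12) and DACH1 (-5.07), with the activin subunit INHBA at least 118-fold lower. DACH1, far lower in parental LoVo-Li, had the largest rise among the genes named for the LoVo-Li lines, at 3.62. Metallothioneins (median -0.80) and antigen presentation genes (-0.65) were lower in parental LoVo-Li, and NF-kB genes (0.56) and cholesterol synthesis genes (0.44) higher. These genes were chosen after their values were seen.

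Of the 5 genes named as highest across the oxaliplatin-selected lines, STEAP1, FZD1 and CDK6 lie near each other on chromosome 7, with probes starting at 89438655, 90542491 and 91879094 (hg17). In A2780/4OHP and A2780/cOHP, FZD1 was at 3.41 and 2.52, CDK6 at 2.83 and 3.02, and STEAP1 at 4.08 and 1.35. This was seen in the values. Shifts of the windows they lie in were not found in these lines, with adjusted p from 0.0990 to 0.999 by a rank test. The 41 genes between 80 and 90 Mb had medians of 0.036 and 0.011, and the 129 between 90 and 100 Mb -0.047 and 0.0069. The boundary at 90 Mb parts STEAP1 from FZD1 and CDK6, and each window holds many other genes. A shift limited to a few neighbours could not be seen in this way and was not tested.

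By a rank test, 25 to 101 of 274 windows of neighbouring genes passed the threshold in every line, so passing it says little of a single region. A median beyond 0.3 in size was found as well in 9 windows of ADDP, 3 of A2780/4OHP and 1 of LoVo-Li/4OHP. Of the 9 in ADDP, 4 had a permutation p under 0.05 after multiplying by all tests (hg17). On chromosome 13, 41 genes between 110 and 120 Mb had a median of -0.79 and 53 genes between 90 and 100 Mb one of -0.51. On chromosome 7, 109 genes between 70 and 80 Mb had a median of 0.47, with 94 above 0. On chromosome 4, 67 genes between 80 and 90 Mb had a median of 0.38. The permutation p was 1e-05 for the first 3, the smallest that 100000 draws can give, and 2e-05 for the last, which multiplied by 1918 tests gives 0.019 and 0.038. Genes were drawn as if independent, so these p are too small where neighbours share regulation.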
